A study of Mus musculus with 24 samples.

How the data were processed

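RNA was measured in C2C12 mouse myoblasts, kept undifferentiated and subconfluent, 48 h after transfection with a non-targeting siRNA (siCont), an siRNA against Keap1 (siKeap1), an siRNA against Fem1b (siFem1b), or the latter pair together (siFem1b/Keap1). Per the labels, total RNA was selected for poly(A), each group held 3 libraries, and each library was sequenced in 2 runs, the second a technical repeat. Per the submitters' processing notes, reads were assigned to mouse transcripts with kallisto 0.44.0 on build mm10. Each of the 24 deposited tables lists an estimated count (expected counts, with reads that fit several transcripts shared between them by an estimate), a length-corrected abundance (TPM) and an effective transcript length for 118489 transcripts. How the authors trimmed or filtered reads was not stated.

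Transcripts were matched by identifier to GENCODE M21 (GRCm38). Of these, 116728 (98.5%) matched, each with the annotated length, and the unmatched transcripts, which were left out, carried between 0.608% and 0.637% of the counts of a library. The deposited estimated counts were summed over the transcripts of a gene and over both runs and then rounded, which gave 35968 genes and between 32.1 M and 43.3 M counts per library. Of the 12 second runs, 12 matched their own first run best, and both runs of a library differed by 2.34 to 2.87 times the variance of counting alone (chi-square per degree of freedom, over genes with at least 20 counts). Deposited TPM values were not tested themselves. They chose the transcript searched for seed matches and weighted the effective lengths of the authors' tool, which enter only one alternative.

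Groups were taken from the labels. Genes were filtered with filterByExpr, which left 14577, and library sizes were scaled by the trimmed mean of M-values (TMM, factors from 0.952 to 1.04). The filter keeps a gene that is expressed in a single group, so a gene low elsewhere can enter through the group where it is high. A negative binomial model with a term per group was fitted to all 12 libraries with edgeR 4.0.16 (robust quasi-likelihood tests, R 4.3.3). The 6 pairwise comparisons of the 4 groups and their interaction, (siFem1b/Keap1 minus siFem1b) minus (siKeap1 minus siCont), were tested 2-sided. P-values were adjusted by Benjamini and Hochberg's method within each comparison, with a threshold of 0.05. Log2 fold changes carry their standard error (SE), and CPM are counts scaled by library size times TMM factor, given as mean and standard deviation (SD). Ratios of genes with few counts in a group were taken from the counts, with an exact Clopper-Pearson interval of 95%, which covers counting error only.

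Gene lists, 40 of them, were tested with camera (limma 3.58.1, preset correlation 0.01, log counts with a prior count of 2), adjusted over the lists of a comparison, and again with the correlation estimated for each list. The lists, comparisons, tests, alternatives and the rule for naming genes were fixed before the data were examined. Genes named were 14 chosen in advance in the comparisons with siCont, up to 10 largest rises and falls (up to 6 in the later pairwise comparisons), the 8 smallest p-values of the interaction, and up to 4 members with the smallest p of each described list. Rises and falls were taken among genes past the threshold with a mean of at least 5 CPM, a given symbol, and all 3 libraries of one group beyond all 3 of the other. A few genes that this rule names are not reported here. Near-identical genes were not merged.

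Alternatives were DESeq2 size factors or library totals alone in place of TMM, the DESeq2 1.42.0 Wald test, limma-voom, no filter on low counts, at least 5 CPM in 3 libraries, an offset for transcript length, the first or second run alone, a block for the replicate number, a fit of the compared groups only, an adjusted p under 0.01, a fold change of at least 1.5, and each library left out in turn. After the data were seen, a fit without genes that hold a seed match, and each of the 12 libraries as the TMM reference, were added. That fit left out genes with a match of either targeting siRNA in the 3' UTR, and kept those with matches elsewhere only. The test was tested on simulated data with 100 genes changed 1.5-fold and 100 changed 2-fold among 13805. For siKeap1 against siCont it recovered 72 and 84 of them, and 11 of all 183 calls were false (6.01%). For the interaction it recovered 58 and 66, and 6 of 144 calls were false (4.17%). The other 16 and 14 calls were true ones, of genes shifted for the test of lists. Few genes were changed in the simulation, mostly in random directions. In the real pairwise comparisons 42.2% to 67.5% of genes were called, so these rates need not carry over.

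The siRNA sequences were located in the annotated transcripts. Seed matches, of 7 bases, pair with guide positions 2 to 8. A single transcript per gene was searched, the protein-coding one with the highest mean TPM. It has a 3' UTR of at least 30 bases in 13251 of 13906 tested protein-coding genes, with Keap1 and Fem1b set aside. Shifts of log2 fold changes were tested with a one-sided rank test (SciPy 1.17.1) and compared with shuffled seeds. These were reorderings of the same bases above a minimum number of genes, and were not otherwise matched for frequency. Tables and figures were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9.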

Results

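RNA was sequenced from C2C12 cells, a mouse myoblast line, the precursor cells of skeletal muscle that can be made to fuse into myotubes. The cells were kept undifferentiated and were taken 48 h after transfection with siRNA. There were 4 groups of 3 libraries: a non-targeting siRNA (siCont), an siRNA against Keap1 (siKeap1), an siRNA against Fem1b (siFem1b), and both targeting siRNAs together (siFem1b/Keap1). KEAP1 is the substrate receptor through which a CUL3 ubiquitin ligase marks NRF2, the transcription factor encoded by Nfe2l2, for degradation. FEM1B is a substrate receptor of CUL2 ubiquitin ligases, and the series places it in the cell's response to reductive stress. The design asks how the transcriptome changes when each receptor is depleted, and whether depletion of both gives the sum of the separate changes. Each of the 12 libraries was sequenced in 2 runs, which were added, and held between 32.1 M and 43.3 M estimated counts, with 18613 to 19905 genes detected. The labels state 3 repeats per group and not whether these were separate cultures, so the p-values measure only the spread between these libraries, which may be technical. That spread was small, with a common biological coefficient of variation of 0.0503 over 14577 tested genes. The first principal component, with 55.5% of the variance, parted the libraries with siFem1b from those without, and the second, with 21.2%, parted those with siKeap1 from those without.

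Keap1 and Fem1b were depleted in each library given the matching siRNA. Keap1 stood at 61.7 ± 1.4 CPM, the counts scaled by library size (mean ± SD, n = 3), in siCont and 9.98 ± 1.30 in siKeap1, which is 16.2% of siCont. It stood at 59.2 ± 3.6 CPM in siFem1b and 9.38 ± 0.19 in siFem1b/Keap1, which are 95.8% and 15.2% of siCont. Fem1b stood at 96.9 ± 4.0 CPM in siCont, 102 ± 4.1 in siKeap1, 13.2 ± 0.42 in siFem1b and 12.7 ± 1.3 in siFem1b/Keap1, so that 13.7% and 13.1% of the siCont level were left in the groups given siFem1b. In single libraries Keap1 lay between 8.58 and 11.1 CPM with siKeap1 and between 56.7 and 63.3 without. Fem1b lay between 11.6 and 14.2 CPM with siFem1b and between 94.0 and 106 without. The siFem1b sequence GAAGAUCAGUGCAGAAUUA matched the coding sequence in exon 2 of 2 of Fem1b, on the minus strand of chromosome 9 (GRCm38, 62796575 to 62796593). The siKeap1 sequence GCGCCAAUGUUGACACGGA matched the coding sequence of Keap1, on the minus strand of chromosome 9 (GRCm38, 21231850 to 21231868), in exon 4 of 6 of 4 transcripts and exon 3 of 5 of another. An antisense gene, Gm16754, covers the same bases in its exon 3 of 3, and reads of Keap1 and of this gene cannot be told apart without strand.

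**Figure D1:**
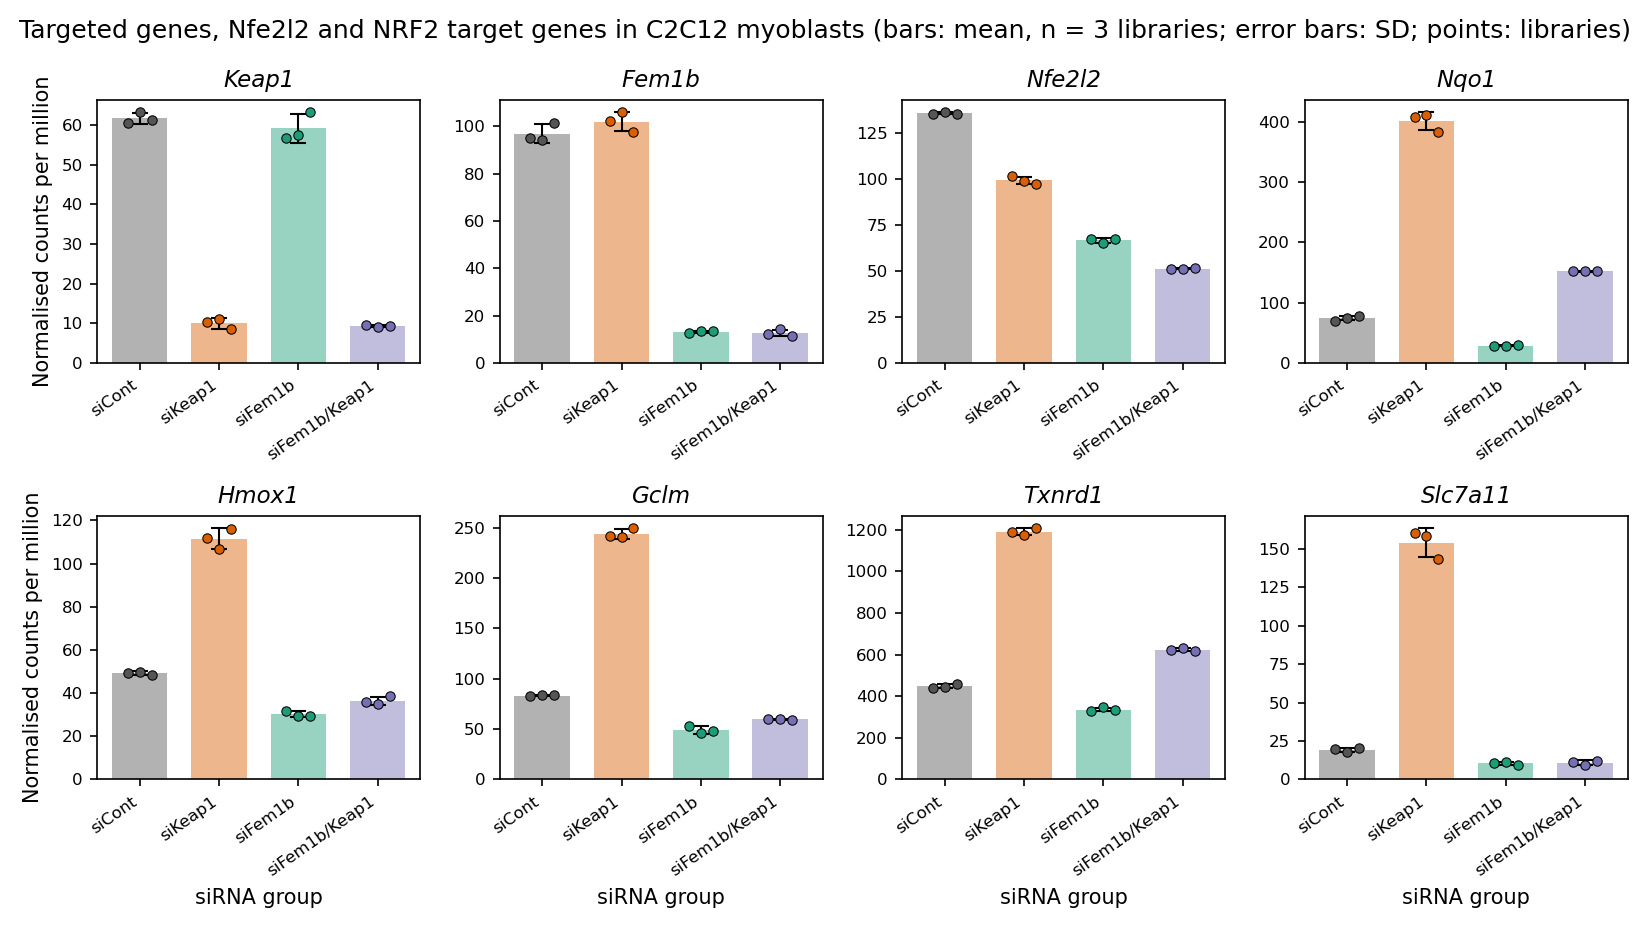
Normalised counts (CPM) of the targeted genes, of Nfe2l2 and of 5 NRF2 target genes (vertical axes, each starting at 0) in the 4 siRNA groups (horizontal axes); bars are means of 3 libraries, error bars are SD and points are libraries. Nqo1 stood at 74.0 CPM in siCont, 401 in siKeap1, 28.4 in siFem1b and 152 in siFem1b/Keap1.

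Depletion of Keap1 raised the genes that NRF2 is known to drive. Nqo1, an NAD(P)H quinone reductase on chromosome 8 (GRCm38, 107388225 to 107403206), rose 5.41-fold (log2 fold change 2.44, SE 0.042, adjusted p = 2.5e-18), from 74.0 ± 3.6 to 401 ± 15 CPM (SD, n = 3). Slc7a11, the cystine transporter subunit that feeds glutathione synthesis, rose 7.93-fold, from 19.4 ± 1.3 to 154 ± 9.3 CPM. Gclm and Gclc, the subunits of the rate-limiting enzyme of glutathione synthesis, rose 2.93-fold and 2.64-fold. Txnrd1, thioredoxin reductase, rose 2.66-fold, the heme oxygenase gene Hmox1 2.27-fold, G6pdx, which opens the pentose phosphate pathway and yields NADPH, 2.10-fold, and the sulfiredoxin gene Srxn1 2.09-fold. Nfe2l2 itself fell, by 0.45 on the log2 scale (SE 0.035, adjusted p = 5.5e-09), from 136 ± 0.55 to 99.4 ± 2.1 CPM. Fnip1, which encodes a partner of folliculin, was lower, by a log2 fold change of -0.27 (adjusted p = 0.0061, and 0.059 in the first run alone), Flcn, which encodes folliculin, had a log2 fold change of -0.05 (adjusted p = 0.44), and Ppargc1a, which encodes PGC-1α, one of 0.52 (adjusted p = 0.17).

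Of the 36 NRF2 target genes measured, 35 rose and 0 fell in siKeap1 (36 and 0 adjusted over the list alone), with a median log2 fold change of 1.19 and a camera adjusted p of 1.2e-29. Where a list below carries 1 adjusted p, its call held with an estimated correlation as well. Gsta4 (5.40-fold) and Gstm1 (3.51-fold), both glutathione S-transferases, were among them. Of 30 genes of glutathione synthesis and use, 22 rose and 0 fell (23 and 1 adjusted over the list alone; adjusted p = 9.5e-12, and adjusted p = 0.062 with an estimated correlation). In the thioredoxin and peroxiredoxin system 13 of 20 rose and 2 fell (16 and 2 adjusted over the list alone), with Cat, which encodes catalase, up 2.97-fold and Prdx6 up 1.90-fold (adjusted p = 4.3e-05, and adjusted p = 0.19 with an estimated correlation). Large rises outside these lists were those of Mmp10, a secreted metalloproteinase (17.8-fold, from 1.73 to 31.2 CPM), the cytokine gene Il1f9 (17.1-fold), Gsta2 (15.4-fold), Gsta1 (12.3-fold), the protease inhibitor gene Slpi (11.4-fold), the aldehyde dehydrogenase gene Aldh3a1 (10.5-fold, from 62.4 to 658 CPM), Cyp11a1 (9.01-fold), Sbsn (8.83-fold) and Cyp1a1 (8.13-fold). Trdc, which encodes a constant region of the T cell receptor, was 16.4-fold higher. Gsta1 and Gsta2 have near-identical copies, and how the authors' counting shared reads between such copies is uncertain.

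Growth and muscle genes went the other way. Of 35 mitosis genes, 34 fell and 0 rose (35 and 0 adjusted over the list alone; adjusted p = 9.5e-12), among them Top2a, which encodes topoisomerase II alpha (1.54-fold lower, from 707 to 460 CPM), and the cyclin gene Ccna2 (1.43-fold lower). Of 36 genes of DNA replication, 28 fell and 0 rose (29 and 0 adjusted over the list alone), with Mcm10 1.91-fold and the cyclin gene Ccne1 1.72-fold lower (adjusted p = 3.4e-08, and adjusted p = 0.13 with an estimated correlation). In contrast 18 of 24 p53 target genes rose and 2 fell (18 and 2 adjusted over the list alone; adjusted p = 5.2e-07). Gdf15, a stress cytokine, rose 2.87-fold and Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, 1.59-fold. Heat shock genes rose in 12 of 19 cases and fell in 1 (12 and 1 adjusted over the list alone; adjusted p = 0.00054), with Hspb8 up 1.64-fold. Of 39 genes of muscle differentiation and contraction, 19 fell and 5 rose (20 and 5 adjusted over the list alone; adjusted p = 0.0049, and adjusted p = 0.22 with an estimated correlation). Myog, which encodes the differentiation factor myogenin, had 4 counts over the 3 siKeap1 libraries and 171 in siCont, a 41.1-fold lower ratio (95% exact Clopper-Pearson interval 15.8 to 153, for counting error only). Myl1, a myosin light chain gene, fell 7.45-fold, whereas Acta1, skeletal alpha-actin, rose 1.96-fold. Further large falls were those of C1qtnf3 (24.1-fold), the IGF-binding protein gene Igfbp5 (9.11-fold, from 1087 to 119 CPM), Stc1 (6.36-fold), decorin, Dcn (4.96-fold), the uracil glycosylase gene Ung (4.49-fold) and Islr (4.39-fold).

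Slc2a1, the glucose transporter GLUT1, fell 2.81-fold and Pdk1, a kinase that restrains pyruvate dehydrogenase, 1.83-fold, within a hypoxia list in which 13 of 21 fell and 3 rose (14 and 4 adjusted over the list alone; adjusted p = 0.0042, and adjusted p = 0.057 with an estimated correlation). SRF and YAP target genes rose in 18 of 23 cases and fell in 4 (18 and 4 adjusted over the list alone), with the matricellular gene Ccn2 up 2.23-fold (adjusted p = 4.7e-05, and adjusted p = 0.26 with an estimated correlation). Markers of other cell types moved too, among those that passed the filter on low counts. Low markers can pass it through the group where they are high, which favours rises there. Of 9 epithelial markers 5 rose and 0 fell (5 and 0 adjusted over the list alone; adjusted p = 0.0049, and adjusted p = 0.062 with an estimated correlation), led by the keratin gene Krt14 (6.44-fold, from 9.70 to 62.4 CPM). All 3 measured macrophage and leukocyte markers rose (3 adjusted over the list alone), Cd68 from 1.56 to 3.59 CPM (adjusted p = 0.018 for the list, adjusted p = 0.17 with an estimated correlation, and 0.052 in the second run alone). In total 6156 genes changed, 2681 higher and 3475 lower, of which 1470 changed by at least 1.5-fold (965 higher, 505 lower). The balance of the total turned with the scaling, with 3021 higher and 2961 lower by library totals alone, and the share of higher genes ran from 43.6% to 50.6% over 12 TMM reference libraries. The 3 libraries of one group lay beyond all 3 of the other for 51.2% of genes, where chance gives 10%. Of the named genes that fell, Ung, Slc2a1 and the YAP target gene Crim1 (1.81-fold lower) hold a 7-base match to the siKeap1 seed in the 3' UTR, and Ccne1 and Stc1 hold one elsewhere in the transcript. Of those that rose, Srxn1 holds one in the 3' UTR and Cyp1a1 one elsewhere.

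Depletion of Fem1b raised muscle genes in cells kept as myoblasts. Myog, on chromosome 1 (GRCm38, 134289989 to 134292548), rose 38.2-fold (log2 fold change 5.26, SE 0.099, adjusted p = 1.1e-17), from 1.57 ± 0.26 to 59.3 ± 2.6 CPM (SD, n = 3). The troponin gene Tnnc2 rose 44.8-fold, the giant sarcomere protein gene Neb 18.2-fold, the myosin light chain genes Mylpf 17.6-fold and Myl1 14.7-fold, Myom3 17.2-fold, Klhl41 16.0-fold and Acta1 9.36-fold, from 6.89 to 64.4 CPM. Of the 39 genes of muscle differentiation and contraction, 35 rose and 3 fell (35 and 3 adjusted over the list alone), with a median log2 fold change of 2.63 and an adjusted p of 1.5e-12. The growth factor gene Igf2 rose 73.5-fold, from 0.315 to 23.5 CPM, the metalloproteinase gene Mmp15 13.7-fold and Dcn 12.7-fold. Genes of myoblast identity rose in 22 of 28 cases and fell in 5 (22 and 5 adjusted over the list alone), with Notch3 (2.20-fold) and the myogenic factor gene Myf5 (2.23-fold) among those that rose (adjusted p = 2.2e-05, and adjusted p = 0.085 with an estimated correlation).

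The NRF2 target genes fell with Fem1b depletion. Of 36, 25 fell and 1 rose (25 and 1 adjusted over the list alone), with a median log2 fold change of -0.40 (adjusted p = 1.4e-07, and adjusted p = 0.085 with an estimated correlation). Nqo1 was 2.61-fold lower (28.4 ± 0.66 CPM, SD, n = 3), Srxn1 1.97-fold, Slc7a11 1.87-fold, Gclm 1.70-fold, Hmox1 1.63-fold, Txnrd1 1.34-fold and G6pdx 1.26-fold. Nfe2l2 was 2.03-fold lower, at 66.8 ± 1.3 CPM. Larger falls were seen for Gsta1 (22.0-fold) and Gsta4 (4.54-fold), and Gsta2 had 14 counts against 832, a 57.5-fold lower ratio (95% exact interval 34.1 to 106). Ftl1, the ferritin light chain gene on chromosome 7 (GRCm38, 45457944 to 45459884), dropped from 3766 to 442 CPM, 8.52-fold (SE 0.064 on the log2 scale, adjusted p = 3.4e-16), and the ferritin heavy chain gene Fth1 was 1.58-fold lower. Of 25 genes of iron and heme handling, 14 fell and 1 rose (14 and 1 adjusted over the list alone; adjusted p = 0.0065, and adjusted p = 0.085 with an estimated correlation). Of 20 genes of NADPH production, 14 fell and 3 rose (14 and 3 adjusted over the list alone), among them the one-carbon enzyme genes Mthfd1l (1.95-fold lower) and Mthfd1 (1.70-fold lower; adjusted p = 0.0020, and adjusted p = 0.090 with an estimated correlation). The prolactin family genes Prl2c2 (8.47-fold) and Prl2c3 (5.13-fold), the chemokine gene Ccl7 (3.85-fold) and Aldh3a1 (3.84-fold) were also among the large falls. The Prl2c genes, Gsta1 and Gsta2, and Ftl1 have near-identical copies, so their single values are uncertain.

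Interferon-response genes rose in 27 of 29 cases and fell in 0 (27 and 0 adjusted over the list alone; adjusted p = 1.5e-07), with the transcription factor gene Irf7 up 6.37-fold, Bst2 2.81-fold and Ddx58, which encodes the RNA sensor RIG-I, 2.24-fold. Cell division genes fell. Of 36 DNA replication genes 34 fell and 1 rose (34 and 1 adjusted over the list alone; adjusted p = 1.6e-10, and adjusted p = 0.085 with an estimated correlation), with Mcm5 1.66-fold lower. Of 35 mitosis genes 33 fell and 2 rose (33 and 2 adjusted over the list alone; adjusted p = 2.1e-08, and adjusted p = 0.085 with an estimated correlation), with Kif20a 2.48-fold lower. In the ATF4 list of the integrated stress response 25 of 35 fell and 6 rose (25 and 6 adjusted over the list alone), among them the serine and glycine enzyme genes Shmt2 (2.01-fold lower) and Phgdh (1.66-fold lower; adjusted p = 0.00019, and adjusted p = 0.23 with an estimated correlation). Lysosomal genes known to be driven by TFEB and TFE3 rose in 26 of 43 cases and fell in 6 (26 and 6 adjusted over the list alone; adjusted p = 0.00062, and adjusted p = 0.33 with an estimated correlation). Gpnmb rose 6.57-fold, the sialidase gene Neu1 2.09-fold and Flcn 1.51-fold, while Fnip1 had a log2 fold change of -0.08 (SE 0.070, adjusted p = 0.31). Ppargc1a was 2.30-fold higher, at 1.62 CPM.

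Genes of protein synthesis and turnover fell by small amounts together. Of 49 cytosolic ribosome genes 45 fell and 0 rose (46 and 0 adjusted over the list alone), with Rpl7a 1.36-fold lower (adjusted p = 1.3e-07, and adjusted p = 0.47 with an estimated correlation). Of 51 mitochondrial ribosome genes 38 fell and 1 rose (38 and 1 adjusted over the list alone), with Mrpl16 1.43-fold lower (adjusted p = 1.1e-05, and adjusted p = 0.47 with an estimated correlation). Of 32 proteasome genes 27 fell and 0 rose (27 and 0 adjusted over the list alone), with Psma5 1.68-fold lower (adjusted p = 2.7e-05, and adjusted p = 0.47 with an estimated correlation). Of 9 epithelial markers that passed the filter 6 rose and 0 fell (6 and 0 adjusted over the list alone), with the keratin gene Krt19 up 2.05-fold to 71.0 CPM. The list's adjusted p was 0.038, and adjusted p = 0.14 with an estimated correlation. It was 0.093 with library totals alone, 0.055 without genes that hold a seed match and 0.059 without siFem1b replicate 3. In total 9047 genes changed, 4373 higher and 4674 lower, and 3078 of them by at least 1.5-fold (2079 higher, 999 lower). With library totals alone in place of TMM factors the split was 5456 higher and 3549 lower. The groups did not overlap for 63.6% of genes, against 10% by chance. Among the named genes that rose, Igf2 holds a 7-base match to the siFem1b seed in the 3' UTR, within a run of 9 paired bases. Ddx58 and Ppargc1a, which rose too, hold one outside the 3' UTR. Among the named genes that fell, Nfe2l2, Srxn1, Ccl7, Kif20a and Shmt2 hold such a match in the 3' UTR. In Nfe2l2 and Ccl7 it lies in a run of 9 paired bases as well. Ftl1 holds one in its coding sequence, and Slc7a11, Phgdh, Mthfd1l and Psma5 hold one outside the 3' UTR, which in Slc7a11 lies in a run of 9 paired bases.

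**Figure D2:**
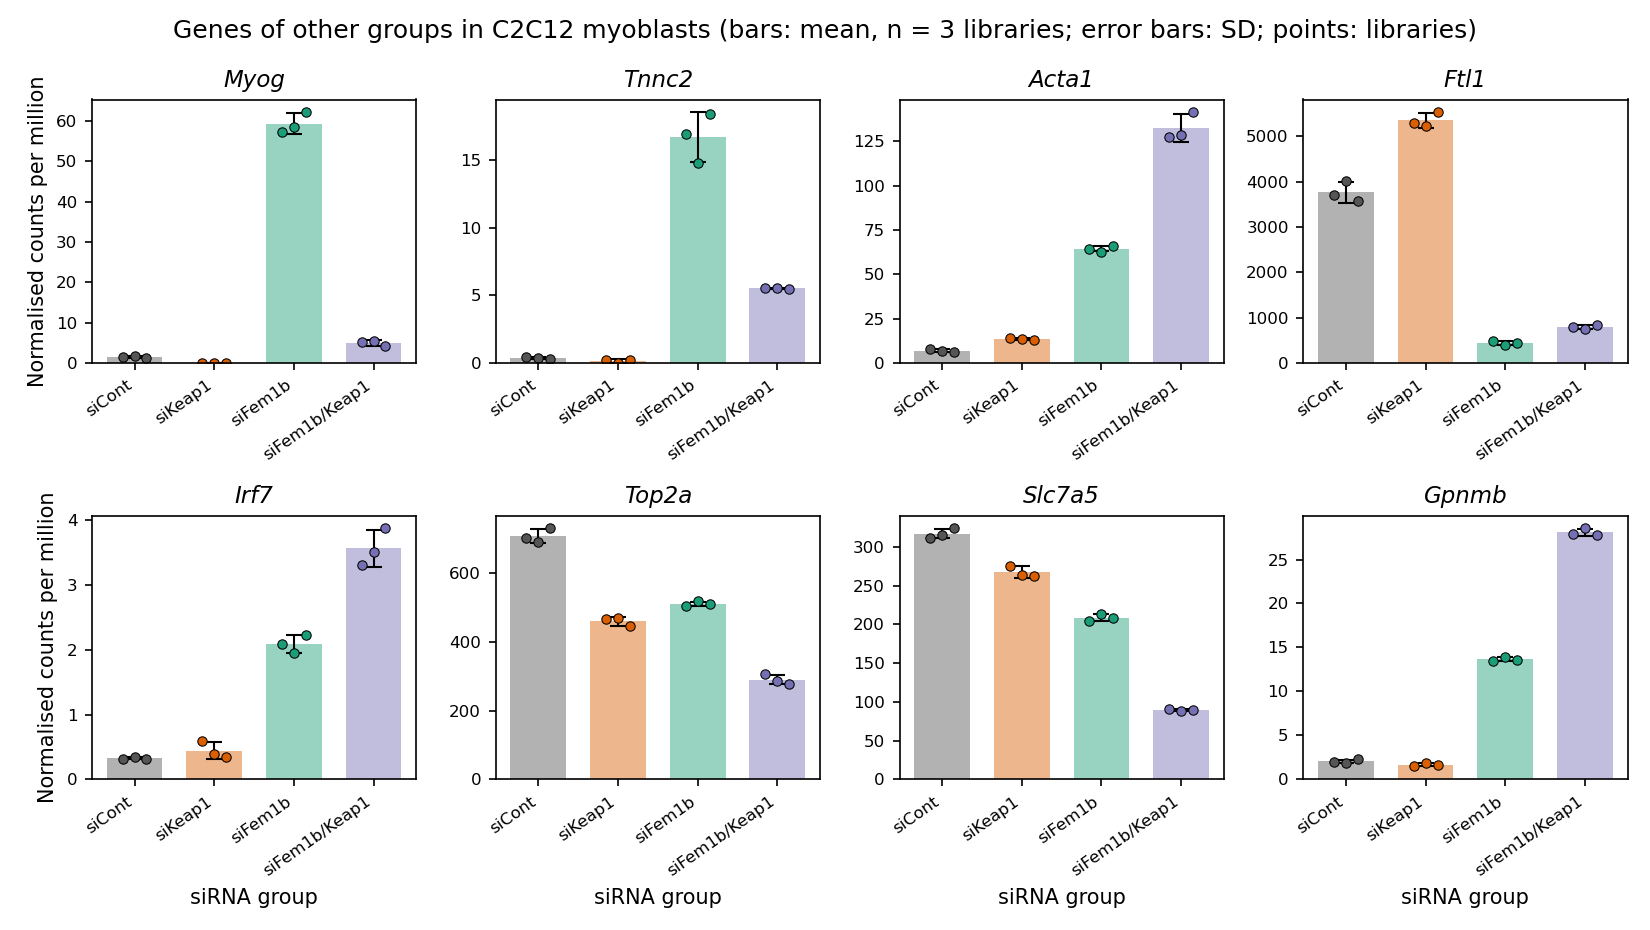
Normalised counts (CPM, vertical axes, each starting at 0) of 8 genes in the 4 siRNA groups (horizontal axes); bars are means of 3 libraries, error bars are SD and points are libraries. Myog stood at 59.3 CPM in siFem1b and 4.96 in siFem1b/Keap1, and Slc7a5 at 317 CPM in siCont and 89.2 in siFem1b/Keap1.

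With both receptors depleted, the NRF2 target genes split. Against siCont, Nqo1 was 2.06-fold higher (log2 fold change 1.04, SE 0.042, adjusted p = 1.1e-13; 152 ± 0.60 CPM, SD, n = 3), G6pdx 1.82-fold, Txnrd1 1.39-fold, the aldehyde oxidase gene Aox1 2.78-fold and the epoxide hydrolase gene Ephx1 2.22-fold higher. Slc7a11 was 1.80-fold, Gclm 1.40-fold, Hmox1 1.35-fold, Srxn1 1.20-fold and Ftl1 4.76-fold lower. Of the 36 genes, 22 rose and 8 fell (22 and 8 adjusted over the list alone; adjusted p = 0.013, and adjusted p = 0.45 with an estimated correlation). Nfe2l2 was 2.65-fold lower, at 51.3 ± 0.29 CPM. In the glutathione list 21 of 30 rose and 7 fell (21 and 7 adjusted over the list alone), with Mgst3 up 2.22-fold and the amino acid transporter subunit gene Slc3a2 down 2.02-fold (adjusted p = 0.016, and adjusted p = 0.49 with an estimated correlation).

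Large rises against siCont were those of Acta1 (19.2-fold, from 6.89 to 132 CPM), the fatty acid-binding protein gene Fabp3 (17.4-fold), the interleukin-1 receptor antagonist gene Il1rn (16.6-fold), Sh3tc1 (15.5-fold), Tnnc2 (14.8-fold), Gpnmb (13.5-fold), the guanosine triphosphatase gene Rab3b (a log2 fold change of 3.46), Lmod1 (10.3-fold), Myom3 (10.2-fold) and Galnt6 (10.2-fold). Of the 39 muscle genes 30 rose and 3 fell (30 and 3 adjusted over the list alone; adjusted p = 4.2e-06, and adjusted p = 0.085 with an estimated correlation), and Myog was 3.22-fold higher. Interferon-response genes rose in 27 of 29 cases and fell in 0 (27 and 0 adjusted over the list alone; adjusted p = 6.0e-08), with Irf7 up 10.8-fold and Ifi35 2.56-fold. TFEB and TFE3 lysosomal genes rose in 38 of 43 cases and fell in 3 (38 and 3 adjusted over the list alone), with the acid glucosidase gene Gaa up 2.19-fold, Neu1 2.65-fold and Tpp1 1.73-fold (adjusted p = 9.1e-08, and adjusted p = 0.12 with an estimated correlation). Flcn was 1.65-fold and Ppargc1a 2.59-fold higher, and Fnip1 had a log2 fold change of -0.02 (adjusted p = 0.78).

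Large falls, beside those of the targeted genes and Ftl1, were those of the neurotrophin receptor gene Ngfr (10.5-fold, from 57.9 to 5.53 CPM), Ung (5.04-fold), Slc2a1 (4.97-fold), the mitochondrial folate enzyme gene Aldh1l2 (4.61-fold), Chic2 (4.57-fold), Tmem65 (4.56-fold) and Lmbrd2 (4.11-fold). Of the 35 ATF4 genes 28 fell and 3 rose (28 and 3 adjusted over the list alone; adjusted p = 3.0e-09, and adjusted p = 0.085 with an estimated correlation). Slc7a5, the large neutral amino acid transporter, was 3.55-fold lower, Shmt2 3.01-fold and Mthfd2 3.00-fold. All 35 mitosis genes fell (35 adjusted over the list alone; adjusted p = 2.9e-14), with Kif20a 3.26-fold and Top2a 2.44-fold lower, and 35 of 36 DNA replication genes fell and 0 rose (35 and 0 adjusted over the list alone; adjusted p = 3.0e-13, and adjusted p = 0.073 with an estimated correlation). Of the 24 p53 target genes 16 rose and 4 fell (16 and 5 adjusted over the list alone), with Btg2 up 6.68-fold and Cdkn1a 2.55-fold (adjusted p = 0.0039, and adjusted p = 0.096 with an estimated correlation).

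Markers of other cell types were higher in the same libraries, among those that passed the filter on low counts. Of 9 epithelial markers 8 rose and 0 fell (8 and 0 adjusted over the list alone; adjusted p = 0.00051). Krt19 rose 3.35-fold, to 116 CPM, Krt14 3.30-fold, and the E-cadherin gene Cdh1 had 440 counts against 14, a 34.4-fold ratio (95% exact interval 20.3 to 63.5). All 6 measured adipocyte markers rose (6 adjusted over the list alone), with Lpl, lipoprotein lipase, up 2.59-fold to 28.3 CPM and Plin4 2.28-fold (adjusted p = 0.0043, and adjusted p = 0.28 with an estimated correlation). Among them Cd36 had 7 counts in siCont and 113 in siFem1b/Keap1. A gene this low passes the filter only through groups where it is high, so that none fell carries little weight. In total 9840 genes changed, 4934 higher and 4906 lower, and 4287 of them by at least 1.5-fold (2660 higher, 1627 lower). With library totals alone the split was 6131 higher and 3747 lower, and the median of all genes lay 0.13 higher on the log2 scale. The groups did not overlap for 70.3% of genes, against 10% by chance. Slc2a1 and Lmbrd2 hold seed matches of both siRNAs in the 3' UTR, Ung one of siKeap1, and Chic2, Tmem65, Shmt2, Kif20a and Nfe2l2 of siFem1b. Srxn1 holds one of each, and Slc7a11, Ftl1 and Top2a hold one of siFem1b outside the 3' UTR. All of these genes were lower. Of the named genes that were higher, Aox1 holds matches of both siRNAs outside the 3' UTR. Ifi35 and Ppargc1a hold matches of siFem1b there, and Gaa, Neu1 and Plin4 of siKeap1.

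**Figure D3:**
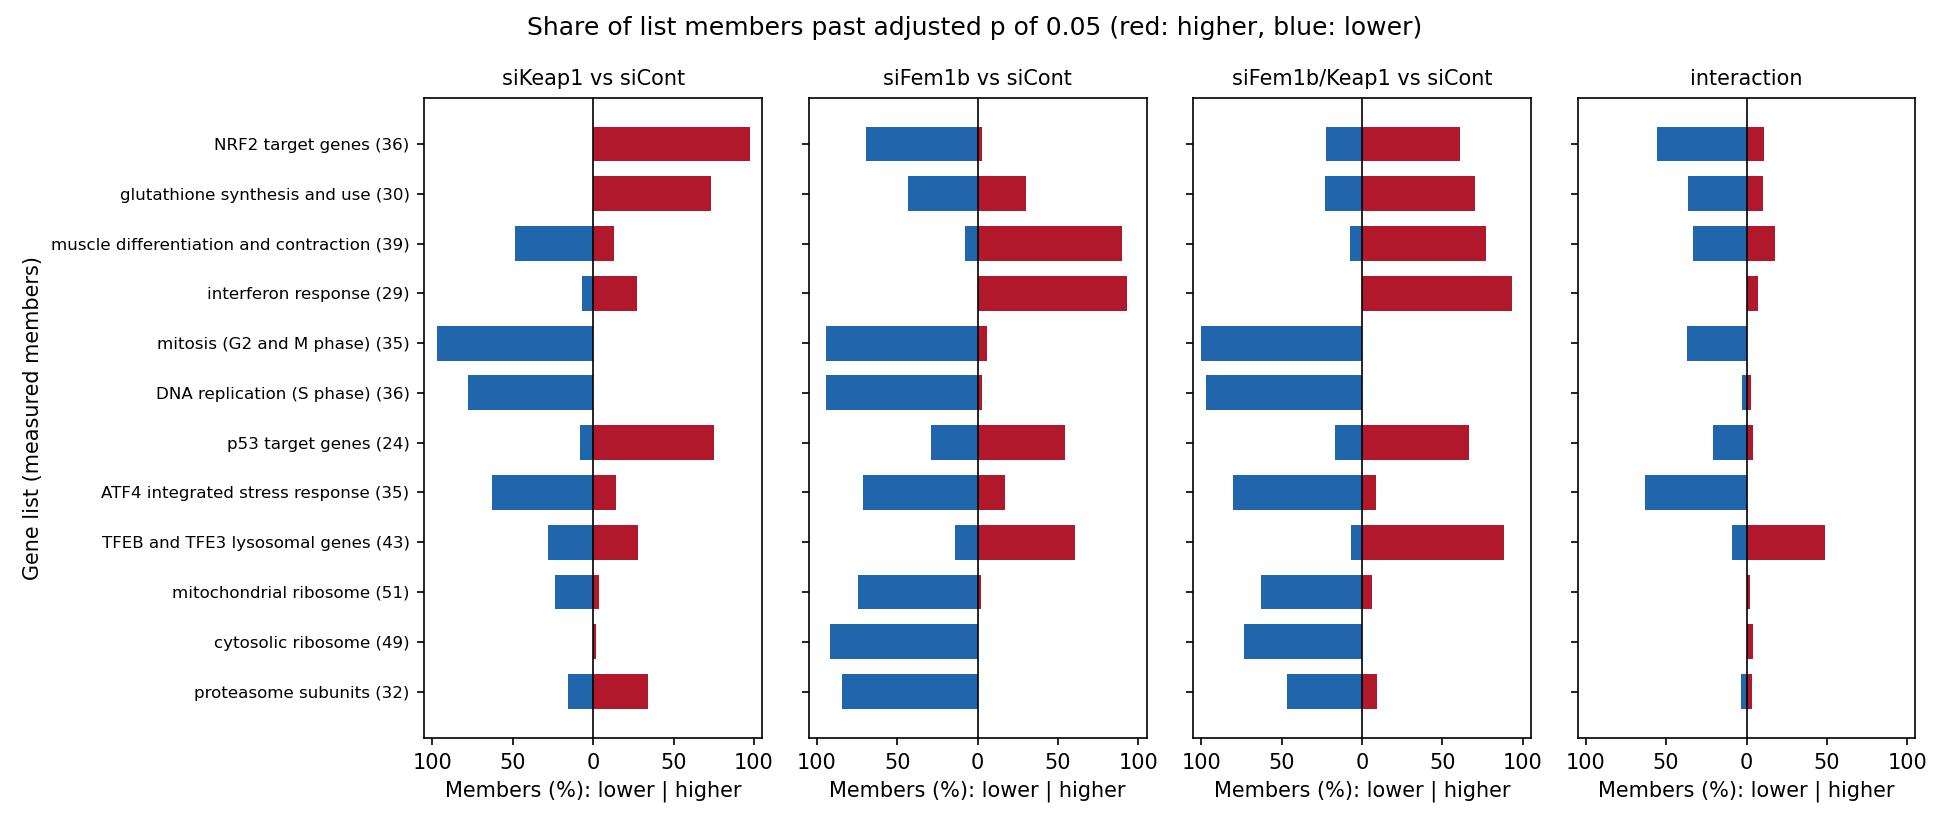
Percent of the measured members of 12 gene lists (vertical axis, with the number of measured members) that were higher (red, to the right) or lower (blue, to the left) at an adjusted p under 0.05 in the 3 comparisons with siCont and in the interaction (horizontal axes, in percent). NRF2 target genes were higher in 35 of 36 cases in siKeap1 and lower in 25 of 36 in siFem1b.

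The effect of Fem1b depletion was also read on the Keap1-depleted background, by comparing siFem1b/Keap1 with siKeap1. Slc7a11 was 14.3-fold lower (log2 fold change -3.84, SE 0.084, adjusted p = 2.8e-15), from 154 to 10.8 CPM, Aldh3a1 10.2-fold, Ftl1 6.76-fold, Gclm 4.09-fold, Gsta4 3.54-fold, Hmox1 3.06-fold and Nqo1 2.63-fold lower. Of 36 NRF2 target genes 33 fell and 1 rose (33 and 1 adjusted over the list alone; adjusted p = 1.1e-12). Gsta2 (21.2-fold), Gsta1 (11.2-fold) and Trdc (7.31-fold) were the other large falls. Of the ATF4 genes 29 of 35 fell and 3 rose (29 and 4 adjusted over the list alone), with Slc7a5 3.00-fold and Slc1a4, another amino acid transporter gene, 2.63-fold lower (adjusted p = 1.6e-09, and adjusted p = 0.072 with an estimated correlation). Heat shock genes fell in 13 of 19 cases and rose in 2 (13 and 3 adjusted over the list alone), with the chaperonin gene Hspd1 1.75-fold lower (adjusted p = 0.0056, and adjusted p = 0.072 with an estimated correlation). Mitosis genes fell in 34 of 35 cases and rose in 1 (34 and 1 adjusted over the list alone; adjusted p = 1.7e-11), and Kif20a was 2.71-fold lower.

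On this background the muscle genes rose in 31 of 39 cases and fell in 1 (32 and 1 adjusted over the list alone; adjusted p = 9.5e-10). Myog had 550 counts against 4, a 145-fold ratio (95% exact interval 56.2 to 533), Igf2 293 against 2, a 154-fold ratio (42.3 to 1280), C1qtnf3 was 57.9-fold and Myl1 37.3-fold higher. Interferon-response genes rose in 25 of 29 cases and fell in 0 (25 and 0 adjusted over the list alone; adjusted p = 3.1e-07), with Stat2 2.07-fold higher. TFEB and TFE3 lysosomal genes rose in 32 of 43 cases and fell in 7 (33 and 7 adjusted over the list alone), with Gpnmb 16.6-fold higher (adjusted p = 8.6e-06, and adjusted p = 0.18 with an estimated correlation). Cholesterol synthesis genes rose in 21 of 25 cases and fell in 3 (21 and 3 adjusted over the list alone), with Hmgcs1 up 1.82-fold (adjusted p = 0.00029, and adjusted p = 0.27 with an estimated correlation). In total 9267 genes changed, 4665 higher and 4602 lower, 3463 of them by at least 1.5-fold (2143 higher, 1320 lower). With library totals alone the split was 5680 higher and 3527 lower, and the groups did not overlap for 69.4% of genes. Slc1a4 and Kif20a, which were lower, and Stat2 and Igf2, which were higher, hold siFem1b seed matches in the 3' UTR. Slc7a11 and Ftl1 hold them outside it.

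The effect of Keap1 depletion on the Fem1b-depleted background was read from siFem1b/Keap1 against siFem1b. Nqo1 was 5.36-fold higher (log2 fold change 2.42, SE 0.045, adjusted p = 7.1e-18), from 28.4 to 152 CPM, Gsta4 6.92-fold, Gstm1 3.84-fold, G6pdx 2.29-fold, Cat 2.33-fold and Txnrd1 1.86-fold higher. Of the 36 NRF2 target genes 30 rose and 0 fell (30 and 0 adjusted over the list alone; adjusted p = 1.8e-19). Gsta1 (24.2-fold), Prl2c2 (8.58-fold), Trdc (8.57-fold) and the serpin gene Serpinb9e (6.95-fold) led the rises, and Gsta2 had 601 counts against 14, a 45.5-fold ratio (95% exact interval 26.9 to 83.7). Most muscle genes stood lower here than in siFem1b. Myog was 11.9-fold lower, Igf2 8.84-fold, the embryonic myosin gene Myh3 7.13-fold, Mylpf 5.30-fold, and the cardiac actin gene Actc1 12.7-fold, and 33 of the 39 muscle genes fell and 4 rose (33 and 5 adjusted over the list alone; adjusted p = 1.0e-09). The muscle regulator gene Myod1 was 1.73-fold lower. Acta1 was among the muscle genes that rose, from 64.4 to 132 CPM, and Myh3 holds a siKeap1 seed match outside the 3' UTR.

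Mitosis genes fell in 35 of 35 cases (35 adjusted over the list alone; adjusted p = 1.8e-19), with Top2a 1.76-fold lower, and ATF4 genes fell in 29 of 35 and rose in 3 (29 and 3 adjusted over the list alone; adjusted p = 9.5e-13), with the glutathione-degrading enzyme gene Chac1 2.91-fold and Slc7a5 2.34-fold lower. Of the 24 p53 target genes 16 rose and 3 fell (16 and 3 adjusted over the list alone; adjusted p = 4.7e-05), with the DNA polymerase gene Polk up 1.52-fold. TFEB and TFE3 lysosomal genes rose in 28 of 43 cases and fell in 2 (29 and 3 adjusted over the list alone), with Gabarapl1 up 1.62-fold and the cathepsin gene Ctsd 1.46-fold (adjusted p = 1.9e-07, and adjusted p = 0.12 with an estimated correlation). All 9 epithelial markers that passed the filter rose (9 adjusted over the list alone, adjusted p = 3.8e-05), with Krt14 2.48-fold higher. Of 3 macrophage and leukocyte markers 2 rose (2 adjusted over the list alone), Cd68 from 2.06 to 5.71 CPM and Cd14 from 9.22 to 13.6 CPM (adjusted p = 0.027 for the list, and adjusted p = 0.15 with an estimated correlation). In total 6284 genes changed, 3104 higher and 3180 lower, 1365 of them by at least 1.5-fold (825 higher, 540 lower). With library totals alone the split was 3463 higher and 2804 lower, and the groups did not overlap for 50.8% of genes.

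The singly depleted groups differed from each other in NRF2 target and muscle genes, among others. In siFem1b against siKeap1, Nqo1 was 14.1-fold, Ftl1 12.1-fold, Gsta4 24.5-fold and Aldh3a1 40.5-fold lower, and all 36 NRF2 target genes were lower (36 adjusted over the list alone; adjusted p = 1.9e-20). Gsta1 (271-fold) and Trdc (62.7-fold) were also lower, and Gsta2 had 14 counts against 12530, a 901-fold lower ratio (95% exact interval 537 to 1648). Muscle genes were higher in 36 of 39 cases and lower in 1 (36 and 1 adjusted over the list alone; adjusted p = 1.5e-13), with C1qtnf3 160-fold, Myl1 109-fold and Dcn 63.0-fold higher. Myog had 6792 counts against 4, a 1687-fold ratio (659 to 6193). In total 9310 genes differed, 4675 higher and 4635 lower, 3596 of them by at least 1.5-fold (2126 higher, 1470 lower). The split was 5395 higher and 3815 lower with library totals alone, and the groups did not overlap for 67.6% of genes.

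Whether depletion of both receptors gave the sum of the separate changes was tested as an interaction, the log2 change from siFem1b to siFem1b/Keap1 minus that from siCont to siKeap1. Slc7a11, Gclm and Hmox1 departed from the sum. Slc7a11 was raised 7.93-fold by Keap1 depletion alone and stood at 10.4 ± 0.96 CPM in siFem1b and 10.8 ± 1.4 in siFem1b/Keap1 (SD, n = 3), an interaction of -2.93 (SE 0.12, adjusted p = 3.7e-10). Gclm had an interaction of -1.27 (SE 0.064, adjusted p = 2.7e-10) and Hmox1 of -0.91. Txnrd1 (-0.52) and Srxn1 (-0.35) departed by less. Nqo1, by contrast, had an interaction of -0.02 (SE 0.060, adjusted p = 0.91) and G6pdx of 0.12 (SE 0.048, adjusted p = 0.11), and Keap1, Fem1b and Nfe2l2 themselves of -0.03, -0.13 and 0.07, none of which passed. Nqo1 and Keap1 changed the sign of these small values when single libraries were left out. Of the 36 NRF2 target genes, 20 had a negative and 4 a positive interaction (21 and 6 adjusted over the list alone; adjusted p = 3.2e-09, and adjusted p = 0.17 with an estimated correlation).

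Of the 35 ATF4 genes, 22 had a negative interaction and 0 a positive one (26 and 1 adjusted over the list alone; adjusted p = 3.0e-20, and adjusted p = 0.051 with an estimated correlation). Slc7a5 (-0.98) stood at 317 CPM in siCont, 267 in siKeap1, 209 in siFem1b and 89.2 in siFem1b/Keap1, and Aldh1l2 (-1.44) and Chac1 (-1.41) were likewise lower with both siRNAs than the sum. TFEB and TFE3 lysosomal genes went the other way, with 21 of 43 positive and 4 negative (24 and 4 adjusted over the list alone; adjusted p = 4.6e-06, and adjusted p = 0.26 with an estimated correlation). Among them Neu1 had an interaction of 0.60 and the autophagy receptor gene Sqstm1, which is also an NRF2 target, of -0.37. The smallest p-values belonged to the glycine transporter gene Slc6a9 (-1.64), Aldh3a1 (-1.40), the lysosomal membrane protein gene Gpr137b (1.09), the alcohol dehydrogenase gene Adh7 (-1.54), the acetate-activating enzyme gene Acss2 (-1.88), Gclm, Slc7a5 and the argininosuccinate synthase gene Ass1 (-1.36). Slc6a9 stood at 27.9, 77.3, 28.8 and 25.6 CPM in siCont, siKeap1, siFem1b and siFem1b/Keap1, and Gpr137b at 161, 141, 109 and 203. Gpr137b holds a siKeap1 seed match in the 3' UTR, Adh7 and Sqstm1 hold one of siFem1b, and Srxn1 holds both. Slc7a11 holds a siFem1b seed match outside the 3' UTR and Neu1 one of siKeap1. In total 1667 genes had an interaction, 374 of them of at least 1.5-fold. The share with a positive interaction ran from 38.1% to 53.4% over 12 choices of the reference library for the TMM factors, so no direction is given for the total, and 841 genes passed with the transcript length offset and 929 in the first run alone.

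Both effects were compared across backgrounds, between comparisons that share no library. Over 14577 genes, which are not independent of each other, the log2 change with Keap1 depletion on the siCont background correlated with that on the siFem1b background with Pearson's r of 0.62 and Spearman's rho of 0.61. Of the genes changed in both, 1810 were higher in both (571 by chance), 2255 lower in both (758 by chance) and 135 opposite. For Fem1b depletion on the siCont and siKeap1 backgrounds r was 0.83 and rho 0.81, with 3593 genes higher in both (1399 by chance), 3817 lower in both (1476 by chance) and 137 opposite.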

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

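Of the tests in this part, the splits of the libraries, the fit without genes that hold a seed match, the change of the TMM reference, the tests on what lowered the NRF2 target genes and those on Ftl1 were chosen only after the result was seen.

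In 28 results the effect of Keap1 depletion differed between the siCont and the siFem1b background by a test of the difference itself, the interaction (edgeR). It was called for 1667 genes. Among genes already named, the interaction in log2 units was -2.93 for Slc7a11, -1.88 for Acss2, -1.64 for Slc6a9, -1.54 for Adh7, -1.40 for Aldh3a1, -1.36 for Ass1, -1.27 for Gclm, -0.98 for Slc7a5, -0.91 for Hmox1, -0.52 for Txnrd1, -0.35 for Srxn1 and 1.09 for Gpr137b. It was 0.33 for Fnip1 (adjusted p = 0.044, from 0.00026 to 0.26 over the alternatives), and that call was lost in 23 of them. It was lost without any single library (0.086 to 0.14) but siCont 2, siKeap1 2, siFem1b 2 and siFem1b/Keap1 3. It was 1.70 for Myog (adjusted p = 0.039, from 0.022 to 0.64), whose siKeap1 level rests on 4 counts. The call of Myog was lost in 15 alternatives, among them without any single library (0.053 to 0.16) but replicate 3 of siCont, siFem1b and siFem1b/Keap1.

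Among the lists, the mean interaction was -0.46 for the ATF4 genes, -0.44 for NRF2 targets, -0.41 for glutathione synthesis and use, -0.35 for muscle differentiation, -0.26 for immediate early genes, -0.17 for mitosis and -0.16 for p53 targets. It was 0.19 for TFEB and TFE3 lysosomal genes, 0.13 for cholesterol synthesis, 0.13 for hypoxia, 0.12 for the cytosolic ribosome, 0.10 for endoplasmic reticulum chaperones and 0.079 for fatty acid oxidation. None of these 13 list calls held with an estimated correlation. The call of fatty acid oxidation was lost in 15 alternatives, 6 of them with 1 library left out (adjusted p = 0.089 without siCont replicate 2, 0.056 without siKeap1 replicate 1, 0.058 and 0.063 without siFem1b replicates 1 and 3, 0.055 and 0.12 without siFem1b/Keap1 replicates 1 and 3). That of hypoxia was lost in the second run alone (0.066), with the replicate block (0.059), without genes that hold a seed match (0.053), and without siFem1b replicate 3 (0.056) or siFem1b/Keap1 replicate 2 (0.059), that of the chaperones without siFem1b replicate 3 (0.058), and that of p53 targets without siKeap1 replicate 3 (0.051).

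Of 40 splits of the 12 libraries into 4 groups of 3, the real one and others drawn at random, 1, the real one, gave as many genes with an interaction by edgeR (1667), and the highest other gave 0. Every other split mixes groups that differ in at least 6156 genes, which enters the spread within the new groups and leaves few calls to be had, so this count says nothing about chance. The pairwise comparisons allow 10 splits each, too few for a share under 0.05. In each of them 1 split, the real one, gave the most genes (6156, 9047, 9840, 9267, 6284 and 9310 in the order of the report), and the highest other gave 0.

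Genes that hold a match to the seed of the siRNA used were lower than genes without one. For siFem1b against siCont the medians differed by -0.149 in log2 units over 1662 genes with a match, lower than all 418 shuffled seeds, whose lowest was -0.0914. For siKeap1 against siCont the difference was -0.148 over 328 genes, against a lowest of -0.0668 among 177 shuffled seeds. Both are consistent with some silencing through the seeds, though 734 of 4420 genes that fell with siFem1b hold a match in the 3' UTR (16.6%), beside 1662 of all 13251 genes searched, and 156 of 3331 that fell with siKeap1 (4.68%), beside 328 of 13251. These libraries used a single siRNA per target, so effects on and off the target stay open for any single gene. The siCont seed, with 3' UTR matches in 3164 genes, gave differences of -0.024 in siKeap1 and 0.014 in siFem1b. Silencing by siCont would make its matched genes higher in these comparisons. Named genes hold siCont matches too, such as Nqo1, which rose in siKeap1, and Ung, which fell, and these are not listed above. A further fit left out genes with a 3' UTR match of either targeting siRNA. In it 7759 genes changed in siFem1b, 7738 of them called in the main fit too. In siKeap1 5132 changed, 4917 of them called in both. The counts of the kept genes were the same, so this overlap was largely set beforehand. It cannot tell whether silencing of a removed gene changed the kept ones. Matches outside the 3' UTR did not remove a gene from that fit. Genes with a match in the coding sequence alone were lower too than genes without any. The medians differed by -0.093 over 1441 genes for siFem1b and by -0.064 over 1075 for siKeap1. With 8-base coding matches they differed by -0.088 and -0.103. For coding matches no shuffled seeds were compared and length was not matched.

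The NRF2 target genes were lower with Fem1b depletion on both backgrounds. Weaker depletion of Keap1 in the double depletion is argued against, as the log2 change of Keap1 from siKeap1 to siFem1b/Keap1 was -0.089 (95% interval -0.25 to 0.073). Seed matches in the target genes themselves are argued against as the whole cause, as the 28 members with no match in the transcript had a median of -0.40, with 20 lower and 1 higher. Igf2, which rose with siFem1b, holds a siFem1b seed match in the 3' UTR within a run of 9 paired bases. Ccl7, which fell, holds one of that length in the 3' UTR, and Slc7a11, which fell too, holds one outside it. Nfe2l2 itself was lower (-1.02), and its 3' UTR holds a siFem1b seed match (GRCm38, chromosome 2, 75675854 to 75675860, exon 5 of 5) within a run of the same length. A direct effect of the siRNA on Nfe2l2 and an effect of FEM1B loss cannot be told apart, because the only siRNA against Fem1b carries this seed.

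Ftl1 fell from 3766 to 442 CPM with siFem1b. Reads moved between Ftl1 and the copies that carry its name are argued against, since these 3 genes together stood at 12.6% of siCont (3610 and 453 CPM by library totals). Copies under other names were not summed, so reads moved to those were not tested. Its coding sequence holds a siFem1b seed match (GRCm38, chromosome 7, 45459607 to 45459613, exon 1 of 4). Silencing through it stays open. The 296 genes with an 8-base match in the coding sequence alone were lower by a median difference of -0.088, far less than Ftl1. The lowest of them beside Ftl1 had a log2 fold change of -3.03, and whether its match caused this was not tested. A single stronger site thus stays possible.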

How the results depend on the processing

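Among these alternatives, the tests without genes that hold a seed match and those with other TMM reference libraries were chosen only after the data were seen. Of the named-gene values over all alternatives, 20733 kept their direction and side of the threshold. In contrast 119 lost their call (for 32 results), 9 gained one (for 2) and 14 turned direction, none of them past the threshold. Many of these genes were picked from the same data for large changes or small p-values, which itself makes lost calls rare. Of the list tests 3492 kept direction and call, 164 lost the call and 2 turned. The lost calls belong to 97 of 122 list results, each of which lost it with an estimated correlation. The counts of changed genes stayed within 1.5 times the reported count in 255 cases and moved further in 10. With a fold of at least 1.5 they were 1470, 3078, 4287, 3463, 1365 and 3596 in the pairwise comparisons in the order of the report, and 374 for the interaction, as the filter itself is stricter. For the interaction the count was 880 at an adjusted p under 0.01, which is stricter too, 929 in the first run alone, which is shallower, and 841 with the transcript length offset, where the cause was not tested.

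Leaving out single libraries gave from 5330 to 6294, 8472 to 9037, 9342 to 10079, 8651 to 9516, 5498 to 6468 and 8724 to 9476 genes in the pairwise comparisons, and from 1259 to 1893 for the interaction. With library totals alone 60.6% of the genes changed in siFem1b were higher and 62.1% in siFem1b/Keap1, against 48.3% and 50.1% with TMM. Over the TMM references the share ran from 43.6%, with the reference used, to 50.6% in siKeap1.

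Values that turned direction were small, and the cause was not tested. Flcn in siKeap1 was 0.13 in the first run alone. Keap1 in siFem1b was 0.038 with library totals alone and 0.0011 with at least 5 CPM in 3 libraries, and Fnip1 in siFem1b was 0.014 with library totals alone. Fnip1 in siFem1b/Keap1 against siCont was 0.099 with library totals alone, 0.040 with at least 5 CPM in 3 libraries, 0.0016 in the first run alone, 0.0047 and 0.0018 with siKeap1 libraries 1 and 2 as TMM reference, and from -0.095 to 0.037 with single libraries left out. The interaction of Keap1 ran from -0.13 to 0.064 and that of Nqo1 from -0.058 to 0.023 with single libraries left out. The mean of the ATF4 list in siKeap1 was 0.00086 in the first and 0.017 in the second run alone.

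No block was planned in the main fit, as the labels state no pairing by replicate number. Libraries of different groups with the same number correlated from -0.08 to 0.12 (18 pairs, with 1 over 0.1). Those with other numbers correlated from -0.16 to 0.17. A block for the replicate number gave 5926, 8891, 9723, 9123, 6055 and 9184 genes in the pairwise comparisons and 1482 for the interaction. It ended the interaction calls of Myog (adjusted p = 0.055), Rpl24 and the hypoxia list, and the calls of hypoxia in siFem1b/Keap1 against siFem1b and of fatty acid oxidation against siCont. It gained that of Rpl22, and turned no direction. Depth limits genes with few counts, such as Myog and Igf2 in siKeap1.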

Other observations

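The tests of lists below were planned, and those without genes that hold a seed match were chosen only after the data were seen. Genes of mitochondrial and lipid metabolism changed beside those described. Of 23 genes of the tricarboxylic acid cycle 17 fell and 1 rose in siKeap1 (18 and 1 adjusted over the list alone; camera adjusted p = 0.0017, and adjusted p = 0.35 with an estimated correlation), with the succinate dehydrogenase gene Sdhb, which holds a siKeap1 seed match outside the 3' UTR, 1.51-fold lower, while pyruvate carboxylase, Pcx, rose 3.47-fold. In siFem1b 15 fell and 1 rose (15 and 1 adjusted over the list alone; adjusted p = 0.015, and adjusted p = 0.47 with an estimated correlation), with Sdhd, which holds a siFem1b seed match, 1.95-fold lower, a call lost in the first run alone (0.067) and with library totals alone (0.15). In siFem1b/Keap1 17 fell and 2 rose (18 and 2 adjusted over the list alone; adjusted p = 0.0020, and adjusted p = 0.45 with an estimated correlation). Genes encoded by mitochondrial DNA rose in 7 of 13 cases and fell in 0 in siFem1b/Keap1 against siCont (7 and 0 adjusted over the list alone), with mt-Nd4 up 1.38-fold (adjusted p = 0.033, and adjusted p = 0.62 with an estimated correlation). That call was lost without siCont replicate 1 (0.059) and without siFem1b/Keap1 replicate 2 (0.058). The share of counts on mitochondrial DNA was 1.74% to 1.93% in siCont and 2.18% to 2.64% in siFem1b/Keap1. Regulators of mitochondrial biogenesis fell in 11 of 19 cases and rose in 2 in siFem1b (11 and 2 adjusted over the list alone), with Tfam, which holds a siFem1b seed match, 1.70-fold lower (adjusted p = 0.034, and adjusted p = 0.14 with an estimated correlation). That call was lost in the first run alone (0.069) and without siFem1b replicate 1 (0.053).

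Fatty acid oxidation genes rose in 14 of 24 cases and fell in 6 in siFem1b/Keap1 against siCont (14 and 6 adjusted over the list alone), with the carnitine transferase gene Cpt1a up 2.22-fold and the uncoupling protein gene Ucp2 7.77-fold (adjusted p = 0.046, and adjusted p = 0.47 with an estimated correlation). The call was lost with the replicate block (0.0503) and without siCont replicate 1 (0.081), siCont replicate 3 (0.061), siFem1b replicate 1 (0.052) or siFem1b/Keap1 replicate 3 (0.053). Cholesterol synthesis genes rose in 15 of 25 cases and fell in 3 in siFem1b (15 and 3 adjusted over the list alone), with Hmgcs1 up 1.56-fold (adjusted p = 0.015, and adjusted p = 0.47 with an estimated correlation). In siFem1b/Keap1 against siCont 18 rose and 4 fell (19 and 4 adjusted over the list alone), with Tm7sf2 up 3.46-fold (adjusted p = 0.013, and adjusted p = 0.47 with an estimated correlation). Chaperones of the endoplasmic reticulum fell in 11 of 23 cases and rose in 0 in siKeap1 (12 and 0 adjusted over the list alone), with Hspa5 1.26-fold lower (adjusted p = 0.020, and adjusted p = 0.34 with an estimated correlation). Of 21 hypoxia genes 13 fell and 4 rose in siFem1b (14 and 4 adjusted over the list alone), with Slc2a1, which holds seed matches of both siRNAs, 2.02-fold lower. The list's adjusted p was 0.015, adjusted p = 0.085 with an estimated correlation, and 0.074 without genes that hold a seed match. ATF4 genes fell in 22 of 35 cases and rose in 5 in siKeap1 (22 and 5 adjusted over the list alone; adjusted p = 0.032, and adjusted p = 0.43 with an estimated correlation), a call lost in the first (0.13) and second (0.065) run alone, where the list's mean turned positive.

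Interferon-response genes rose in 8 of 29 cases and fell in 2 in siKeap1 (8 and 2 adjusted over the list alone; adjusted p = 0.027, and adjusted p = 0.18 with an estimated correlation), a call lost in the first run alone (0.19) and without siCont replicate 3 (0.063). Of 6 adipocyte markers that passed the filter 4 rose and 0 fell in siFem1b (4 and 0 adjusted over the list alone), with Plin4 1.97-fold higher (adjusted p = 0.039, and adjusted p = 0.47 with an estimated correlation). That call was lost with library totals alone (0.059), without genes that hold a seed match (0.13), without siCont replicate 1 (0.054) and without siFem1b replicate 1 (0.064). Cytosolic ribosome genes fell in 36 of 49 cases and rose in 0 in siFem1b/Keap1 against siCont (36 and 0 adjusted over the list alone; adjusted p = 0.00085, and adjusted p = 0.67 with an estimated correlation), and mitochondrial ribosome genes fell in 32 of 51 and rose in 3 (32 and 3 adjusted over the list alone; adjusted p = 0.00069, and adjusted p = 0.62 with an estimated correlation).

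In the interaction, 13 of 35 mitosis genes were negative and 0 positive (17 and 0 adjusted over the list alone; adjusted p = 3.2e-08, and adjusted p = 0.17 with an estimated correlation). Of 39 muscle genes 13 were negative and 7 positive (18 and 7 adjusted over the list alone; adjusted p = 0.00015, and adjusted p = 0.20 with an estimated correlation), with Mylpf at -1.93 and Myl1 at 1.35. Of 20 immediate early genes 9 were negative and 2 positive (10 and 2 adjusted over the list alone), with Atf3 at -0.94 (adjusted p = 0.00015, and adjusted p = 0.39 with an estimated correlation). No camera call was made in any of the 7 comparisons for the genes of respiratory complex I (smallest adjusted p 0.34), respiratory complexes II to IV (0.072), ATP synthase (0.20), glycolysis (0.063), fatty acid synthesis (0.17), extracellular matrix (0.11), NF-kB (0.57), histones (0.094), KEAP1 and FEM1B ligases and substrates (0.21), osteoblasts (0.73) or endothelium (0.18).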
